A study of Homo sapiens with 45 samples.

How the data were processed

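The series covered human colorectal adenomas and carcinomas and HCT116, an established colorectal carcinoma cell line. Per the labels, H3K4me2, a histone mark of promoters and enhancers, was profiled by ChIP-seq in 10 adenomas and 10 matched carcinomas, whose shared replicate number gives the pair. CNOT3, a subunit of the CCR4-NOT complex, was profiled by ChIP-seq in 2 of the carcinomas and in HCT116. RNA-seq was made of HCT116 with a control shRNA (3 samples) and with an shRNA against CNOT3 (3 samples). The 16 input DNA libraries, 8 of adenomas and 8 of carcinomas, were not analysed here. Per the labels' protocols, tissue for H3K4me2 was treated with micrococcal nuclease, and material for CNOT3 was cross-linked with formaldehyde and sonicated.

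Per the submitters' processing notes, Bowtie2 2.1.0, TopHat2 2.0.9, MACS2, Cufflinks 2.2.1, Cuffnorm and Cuffdiff were used with the hg19 genome, and which tool made which file was not given in the sources used here. The authors deposited 1 peak list per ChIP-seq sample. H3K4me2 lists held positions alone, with no value per peak and no percent or other unit. CNOT3 lists held a score per peak from the authors' peak caller, whose scale was not given in the sources used here and which was at least 50 in each list. For RNA-seq the authors deposited FPKM per gene and library, and a table of their own comparison with FPKM per group, a log2 fold change, a test score, a p-value and a q-value per gene. Depth could not be read from peak lists, and FPKM gave no counts. From the steps between low FPKM values, estimated on 1072 to 1424 genes, 1 read was worth 0.41 to 1.11 log2 units more in the other 5 libraries than in control replicate 3.

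The coordinates of the CNOT3 lists were checked against hg19 before use. The last gene of chromosome 19 in the deposited expression table ended at 59095762, whereas the HCT116 list ran to 63785408 (262 of 3275 peaks on chromosome 19 lay beyond that gene) and that of carcinoma replicate 2 to 63766607 (72 of 647). Those 2 lists were therefore not on hg19 and were compared with each other alone. The CNOT3 list of carcinoma replicate 9 and all H3K4me2 lists fitted hg19. Every test that joined CNOT3 peaks to genes, H3K4me2 or RNA used carcinoma replicate 9 in place of HCT116, a change made after the lists had been seen. No hg19 transcript starts were used here. Gene ends were both ends of the 19650 distinct autosomal loci of the deposited expression table, with a window of 2 kb. Overlapping genes that share a locus there were counted as 1 locus. Tissue comparisons used the 22 autosomes.

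For H3K4me2, the log2 ratio of peak numbers, the percent of peaks at locus ends, the percent of a gene list's loci with a peak and the percent of CNOT3 peaks with an H3K4me2 peak were compared by exact two-sided sign-flip permutation tests over 10 pairs, whose smallest p is 0.00195. The values of gene lists and of CNOT3 peaks were first taken relative to loci or regions found in as many of the 20 lists. Single loci were compared by an exact two-sided sign test over discordant pairs, and loci with a peak in at least 5 more or fewer carcinomas than adenomas were counted. Overlap was at least 1 bp, with 100 circular shifts of the peaks within chromosomes as background and 95% Wilson intervals, which cover counting error only. CNOT3 binding of gene lists was tested by Fisher's exact test, two-sided, against autosomal genes with FPKM of at least 1 in HCT116 controls. Peak lists were processed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

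RNA was tested with limma 3.58.1 with trend, in R 4.3.3, on log2(FPKM + 1), for genes of chromosomes 1 to 22 and X with a mean FPKM of at least 1 over the 6 libraries. Entries on other chromosomes, 1375 in number, were left out. Adjusted p is Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale and understate changes of low genes. The 24 gene lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation beside it. Labels did not say whether the RNA samples were separate cultures, so p-values measure the spread between these samples, which may be technical.

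Groups, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. Named RNA genes were CNOT3, then per direction the 12 genes with the largest log2 fold change among those past the threshold whose groups did not overlap, then up to 4 members per list by smallest p. Named H3K4me2 loci were the 10 per direction with the largest difference in number of marked carcinomas and adenomas, and up to 4 per list. Named CNOT3 genes were the 10 whose ends held the highest-scoring peaks, and up to 4 bound members per list. A few items that this rule names are not reported here. Other members named beside list counts were chosen after their values were seen.

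The RNA procedure was tested on simulated data of 11418 genes for the comparison of depleted with control cells. Of 100 genes changed by 1 on the log2 scale 50 were recovered, and of 100 changed by 2, 98. Of 156 calls 8 were false. The simulated noise was independent between genes, whereas the real libraries differed from each other along gene span, as given below. These rates therefore need not hold for the real calls. The paired test was tested on simulated data for an H3K4me2 list of 28 loci over 10 pairs with assumed marking shares. It passed in 5% of 200 runs with no difference and in 98.5% with 20 percentage points added. Alternatives covered the pseudocount, the filter on low FPKM, the replicate number as a term, equal library medians, limma without trend, removal of a trend along gene span, omission of small RNA genes, stricter peak lists, list length, window, overlap, pairing, pairs by list format and each replicate left out. Whether the RNA replicate numbers pair the samples was checked by the correlation of deviations from the group means, and they were not treated as pairs.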

Results

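The data comprised 20 H3K4me2 peak lists from 10 pairs of colorectal adenoma and carcinoma, 3 CNOT3 peak lists (carcinoma replicates 2 and 9, and the colorectal carcinoma cell line HCT116) and 6 RNA-seq libraries of HCT116 with control or CNOT3 shRNA. H3K4me2 lists held 575 to 139105 autosomal peaks in adenomas (median 46304) and 11360 to 165218 in carcinomas (median 55262). The CNOT3 lists held 8930, 20032 and 37010 peaks in carcinoma replicate 2, carcinoma replicate 9 and HCT116. The FPKM table listed 24631 genes on chromosomes 1 to 22 and X, and 7878 to 8920 of them were listed at 0 in a library. The sequencing depth behind the peak lists and the FPKM values is unknown.

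The first comparison asked how the H3K4me2 landscape differed between adenomas and carcinomas. H3K4me2 lay at the ends of 53.4% ± 20.9 (SD, n = 10) of gene loci in adenomas and 53.6% ± 15.2 (SD, n = 10) in carcinomas. The adenoma mean includes the list of pair 3, which marked 1.44% of loci, where the next lowest adenoma marked 37.3%. That list also enters the adenoma means of the gene lists below. These 2 means were not compared without pair 3. Of the peaks, 42.9% ± 11.01 lay within 2 kb of a locus end in adenomas and 43.6% ± 11.5 in carcinomas. Neither the share of peaks at ends (mean paired difference 0.739 ± 10.4 percentage points, SD, higher in 5 of 10 pairs, p = 0.816) nor the number of peaks (mean log2 ratio 0.37 ± 1.47, higher in 6 of 10 pairs, p = 0.648) differed by more than the spread between pairs, by exact two-sided permutation tests. Lists came in 2 formats that followed the pair. The lists of pairs 1 to 5 held 575 to 42604 peaks and those of pairs 6 to 10, sorted by position, 50004 to 165218. Within the 5 pairs sorted by position the mean log2 ratio of peak numbers was 0.08 (exact permutation p = 0.812) and the difference in share -0.0231 points (p = 1). Within the other 5 they were 0.65 (exact permutation p = 0.875) and 1.5 points (p = 0.688), where 5 pairs cannot give a p below 0.0625. Without pair 3, whose adenoma list was the shortest, both differences changed sign, to -0.07 and -1.17 points.

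RSPO2 and TRIM29 were each marked in 5 more carcinomas than adenomas, the largest difference at any locus. RSPO2, which encodes a secreted enhancer of Wnt signalling (chromosome 8, 108911544 to 109095913, hg19), held H3K4me2 at an end in 4 adenomas and 9 carcinomas, with 5 pairs gaining and 0 losing it (exact sign test p = 0.0625). TRIM29 (chromosome 11, 119981994 to 120008863, hg19) was marked in 3 adenomas and 8 carcinomas (exact sign test p = 0.125). Another 14 loci were marked in 4 more carcinomas and 50 loci in 4 fewer, so those named below are a choice among equal differences, by fewer pairs against the direction, then more lists marked, then symbol. CLEC11A was marked in 5 adenomas and 9 carcinomas, GPR85 and TSPY26P in 4 and 8, AMZ1, ANKMY1 and LOC100507073 in 3 and 7, and LINC01333 and the shared locus of ATF5, IL4I1 and NUP62 in 2 and 6. In the other direction, LGALS3BP, GSDMB, PNPLA3, GPRC5C, ATP9B, IQCC, MRPL16, PVRL3-AS1, UBE2U and ZNF91 were each marked in 9 adenomas and 5 carcinomas. With the threshold of 5 lesions, 2 loci were marked in more carcinomas and 0 in fewer. Without pair 3, whose adenoma list marked 1.44% of loci, 0 loci reached that threshold in more carcinomas. The same held without pair 1, 5 or 8. Of 15566 loci marked in some but not all of the 20 lists, 0 had a sign test p under 0.05 and every adjusted p was 1. Of the 19650 loci, 47.2% were marked in equal numbers of adenomas and carcinomas and 87.7% within 1. Both shares include the 3952 loci (20.1%) marked in no list, which are equal by definition.

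Gene lists for colon cell types and pathways were compared relative to loci marked equally often. Genes of absorptive colonocytes were marked at 58.2% ± 27.6 (SD, n = 10) of 28 loci in adenomas and 51.1% ± 26.7 in carcinomas. VIL1, a protein of the brush border, was marked in 9 adenomas and 6 carcinomas, CEACAM7 in 6 and 3, and CDX2, an intestinal transcription factor, in 7 and 9. HOX genes, regulators of position along the body axis, were marked at 61.03% ± 31.6 of 29 loci in adenomas and 70.0% ± 16.7 in carcinomas, with HOXB7 in 7 adenomas and 10 carcinomas and HOXD8 in 6 and 9. Pluripotency factors were marked at 37.8% ± 16.01 and 33.9% ± 10.2 of 23 loci. The adjusted differences were -4.95 ± 6.26 percentage points for the colonocyte list (lower in 7 of 10 pairs, permutation p = 0.0449), 10.2 ± 15.02 for HOX genes (higher in 7 of 10, permutation p = 0.0605) and -3.43 ± 5.57 for pluripotency factors (permutation p = 0.082), each with an adjusted p of 0.547. In the 5 pairs sorted by position the HOX difference was -0.0452 points (exact permutation p = 0.938), and in the other 5 it was 20.1 points (higher in 5 of 5, exact permutation p = 0.0625, the smallest possible). The colonocyte difference was -1.06 points with the wider 50% of each list. Of 24 lists 0 passed after adjustment (adjusted p 0.547 to 0.957), and 1 had a permutation p under 0.05.

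Lists of secretory, stem, stromal and immune cells showed no difference past the test either. Goblet and enteroendocrine genes were marked at 46.5% ± 26.9 (SD, n = 10) of loci in adenomas and 40.9% ± 25.1 in carcinomas, with MUC2, the main intestinal mucin, in 5 adenomas and 3 carcinomas and CLCA1 in 4 and 1. Intestinal stem cell and Wnt target genes were marked at 64.4% ± 29.6 and 66.7% ± 18.7, with the Wnt target EPHB2 in 6 adenomas and 9 carcinomas. Markers of fibroblasts and smooth muscle were at 34.8% ± 19.4 and 34.0% ± 16.6, endothelial markers at 30.8% ± 18.96 and 28.3% ± 19.7, myeloid markers at 23.5% ± 15 and 24.2% ± 16.3, and T and B lymphocyte markers at 27.3% ± 27.0 and 27.3% ± 25.5. Cell cycle and E2F target genes were marked at 79.4% ± 29.5 and 77.8% ± 22.9, with MKI67 in 8 adenomas and 10 carcinomas, and interferon response genes at 82.3% ± 31.6 and 86.7% ± 15.7.

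**Figure D1:**
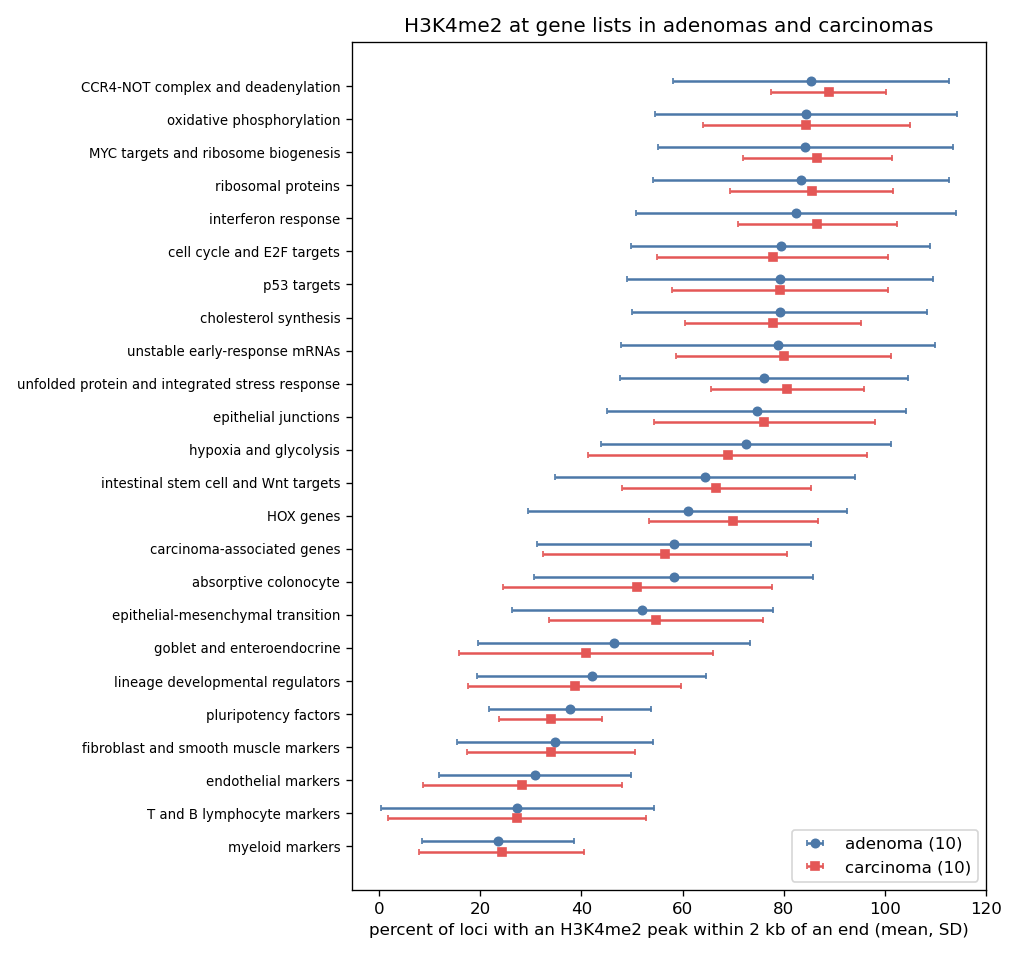
Percent of each gene list's loci with an H3K4me2 peak within 2 kb of an end, in 10 adenomas (circles) and 10 carcinomas (squares), as mean with SD as horizontal bars, for 24 lists. The SDs of both groups overlap in each list, and the colonocyte list stands at 58.2% in adenomas and 51.1% in carcinomas. Adenoma means include replicate 3, which had H3K4me2 at 1.44% of all loci.

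CNOT3 binding was mapped to ask where this complex subunit sits relative to H3K4me2. In carcinoma replicate 9, 83.6% of 20032 CNOT3 peaks (95% Wilson interval 83.1 to 84.1) overlapped an H3K4me2 peak of the same carcinoma, against 10.9% after circular shifts. H3K4me2 of the matched adenoma overlapped 73.6% of them (shifted 8.80%). The adenoma list held 119259 H3K4me2 peaks and the carcinoma list 165218, the most of any carcinoma, so the 2 shares are not of lists of equal length. Conversely, 18.4% of the H3K4me2 peaks of that carcinoma overlapped a CNOT3 peak (shifted 2.04%). CNOT3 peaks of carcinoma replicate 2 lay at HCT116 CNOT3 peaks in 68.5% of cases (67.5 to 69.5; shifted 2.97%), and 15.3% of HCT116 peaks lay at a peak of that carcinoma (14.9 to 15.7; shifted 0.707%). There was 1 library per source, so none of these shares has a replicate check. With at least 50% of the HCT116 peak covered the share fell from 15.3% to 4.53%.

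**Figure D2:**
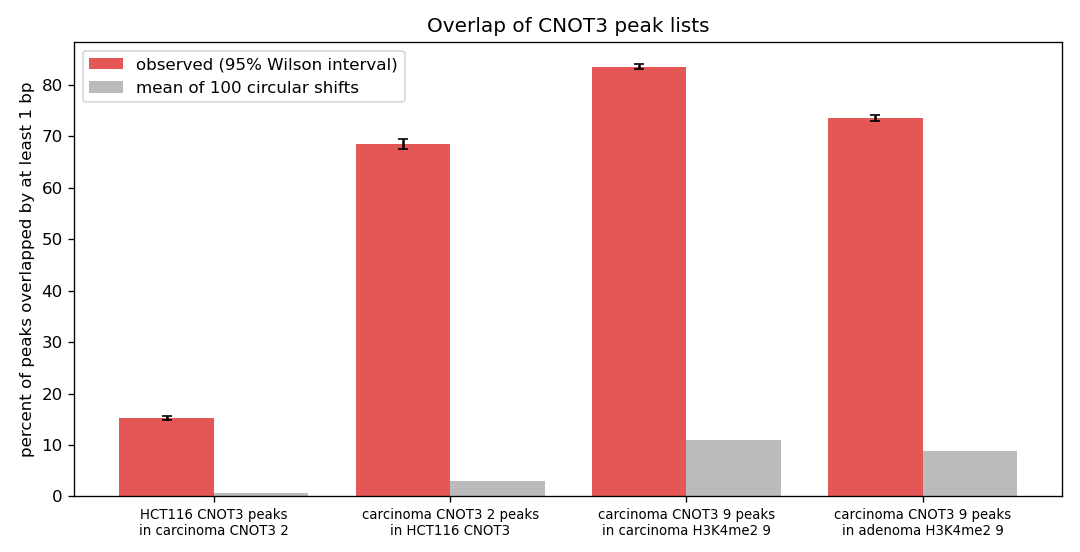
Percent of CNOT3 peaks overlapped by at least 1 bp by another peak list (tall bars, with 95% Wilson intervals) and the mean of 100 circular shifts (grey bars), with 1 library per list. The 4 observed shares are 15.3%, 68.5%, 83.6% and 73.6%, each above its shifted value.

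Gene ends were a frequent site of CNOT3 in carcinoma replicate 9. Of its peaks, 59.0% (95% Wilson interval 58.3 to 59.7) lay within 2 kb of a locus end, 6.87 times the share after circular shifts, and 11050 of 19650 loci (56.2%) were bound. The highest scores, as the authors' peak caller gave them, stood at MIR3648 and MIR3687 (peak on chromosome 21, 9825327 to 9827694, score 1282.58), ZBTB7A, which encodes a zinc finger repressor (chromosome 19, 4057698 to 4068173, score 1045), FBXW5 and C8G (score 924.31), NRARP and EXD3 (score 854.62), PTMA (score 811.35), and IRS2, an adaptor of insulin signalling (score 786.78), all hg19. The input DNA was not analysed here, so high signal without CNOT3 binding was not checked at these sites. H3K4me2 of the same carcinoma marked 96.7% of bound and 42.5% of unbound loci.

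Among genes expressed in HCT116 controls, interferon response genes were bound less often than others. CNOT3 lay at 9 of 24 of them (37.5%) against 81.5% of 10773 other genes (odds ratio 0.136, Fisher's exact test, adjusted p = 5.89e-05 over 24 lists). ISG15, ISG20 and OAS3 were among those bound, and IFIT1, IFIT2, IFIT3, OAS1 and IFI44 were not, the latter named after their values were seen. All 24 loci held H3K4me2 in that carcinoma, as did 94.8% of the others. The other 23 lists did not pass, including p53 targets (24 of 25 bound, adjusted p = 0.556), unstable early-response mRNAs (30 of 33, adjusted p = 0.898), cell cycle and E2F targets (26 of 32, adjusted p = 1) and T and B lymphocyte markers (0 of 3, adjusted p = 0.0768). With the upper 50% of peaks by score the early-response list was also called, with 28 of 33 bound (adjusted p = 0.0446).

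H3K4me2 at the CNOT3 peaks of carcinoma replicate 9 was then compared between lesions. An H3K4me2 peak overlapped 49.4% ± 23.7 (SD, n = 10) of the 20032 CNOT3 peaks in adenomas and 48.3% ± 23.6 in carcinomas. Relative to regions covered in as many lists, the paired difference was 0.319 ± 6.03 percentage points (higher in 5 of 10 pairs, permutation p = 0.869), less than the spread between pairs.

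In the RNA-seq comparison, CNOT3 (chromosome 19, 54641436 to 54663481, hg19) measured 35.4, 41.7 and 28.1 FPKM in control HCT116 cells and 4.02, 6.70 and 6.57 FPKM in cells with the CNOT3 shRNA. It fell from 35.1 ± 6.82 to 5.77 ± 1.51 FPKM (SD, n = 3 each), a log2 fold change of -2.42 with SE 0.23 (limma, adjusted p = 0.00432). The authors' deposited table gave a log2 fold change of -2.60 with q = 0.000626. SLC2A3, KRT7 and ITGA2 were among the genes that rose most. SLC2A3, a glucose transporter, rose from 1.68 ± 0.426 to 43.7 ± 7.82 FPKM (log2 fold change 4.06, SE 0.20, limma adjusted p = 0.000182). KRT7, a keratin of simple epithelia, rose from 17.7 ± 9.03 to 148 ± 7.71 FPKM (3.11), and ITGA2, a collagen-binding integrin subunit, from 3.74 ± 2.18 to 33.1 ± 8.77 (2.91). CPA4 (3.10), KRTAP2-3 (2.94), CLCF1 (2.86), C1orf116 (2.74), ANGPTL4 (2.56) and GRAMD3 (2.49) rose as well. SPC24, a kinetochore subunit, fell from 48.1 ± 16.8 to 5.14 ± 1.22 FPKM (-2.96, limma adjusted p = 0.00449). BCYRN1, whose entry spans a locus of 518928 bp, fell by 3.33 on the log2 scale. The authors' deposited table did not mark BCYRN1 as significant (q = 0.153).

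Small RNA genes made up most of the other extreme values. SNORD32A, MIR4674, SNORD88A, SNORA69, SNORA20 and SNORA71D were listed at 0 in the 3 depleted libraries, with control values from 8.08 FPKM (SNORA71D) to 3412 FPKM (SNORD32A). SNORD35A (338 FPKM), SNORD88C (149), SCARNA22 (36.5) and RNU6ATAC (15.8) were above 0 in depleted replicate 2 alone. In the other direction MIR6807 was listed at 0 in the 3 controls and measured 154, 251 and 169 FPKM in depleted cells, and SNORD83B was at 0 in 2 controls. Many of these genes lie inside other genes, whose reads cannot be told apart from theirs, so their values are uncertain. The authors' deposited table marked none of the small RNA genes named here as significant (q from 0.0792 for MIR4674 to 0.466 for SNORD35A). Of 193 small RNA genes tested 4 rose and 20 fell, and 9 to 26 fell without any 1 library, fewest without depleted replicate 1 and most without control replicate 3.

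In all, 1215 genes rose and 1613 fell of 11418 tested (limma, adjusted p under 0.05), 548 and 737 of them by more than 2-fold. Groups did not overlap in 5974 genes (52.3%, where chance gives 10%). The authors' deposited table marked 4844 genes as significant, and 2573 of the 2828 called here were among them with the same direction and 0 with the opposite. The share of summed FPKM held by the entry with the highest value, MIR6723, differed between libraries. It was 10.0%, 9.22% and 21.8% in control replicates 1, 2 and 3, and 25.2%, 23.3% and 23.5% in depleted replicates 1, 2 and 3. On the first principal component control replicate 3 (-6.85) lay between the other controls (-41.4 and -71.2) and the depleted libraries (30.2 to 56.4). The count depended on single libraries. It was 54 without control replicate 1, 6641 without control replicate 3, and 123, 255 and 405 without depleted replicates 1, 2 and 3. Changes of more than 2-fold were 30 up and 24 down without control replicate 1, and 1139 and 1391 without control replicate 3.

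**Figure D3:**
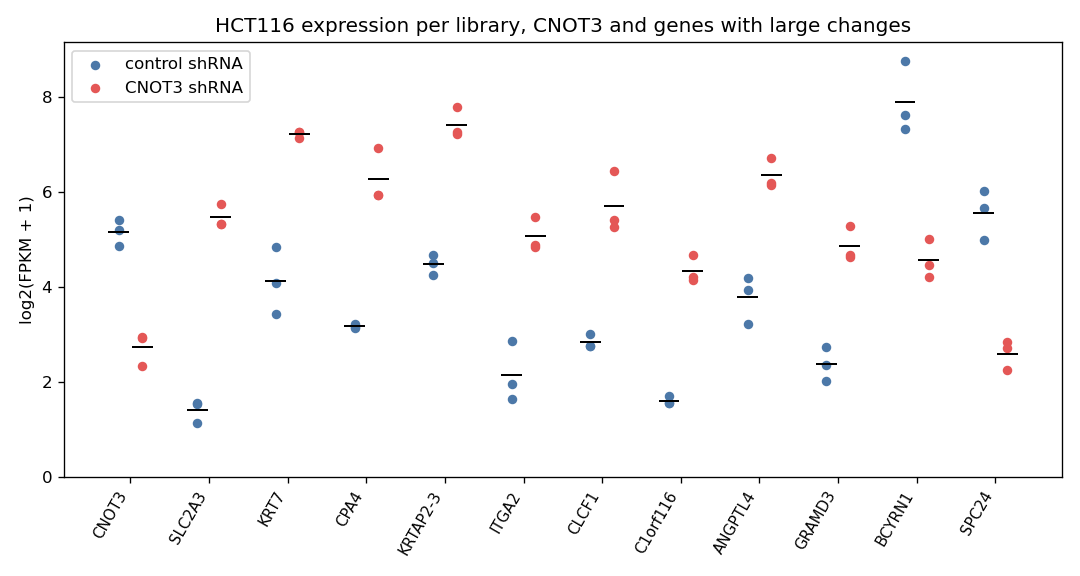
Expression as log2(FPKM + 1) in each of the 3 control shRNA and 3 CNOT3 shRNA libraries (points) with group means (bars), for CNOT3 and genes among those with the largest changes that are not small RNAs. CNOT3 lies at 28.1 to 41.7 FPKM in controls and 4.02 to 6.70 FPKM after depletion. The other genes were chosen among those whose groups did not overlap, so their separation follows from the choice.

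Most of the cell cycle genes tested fell. Of 32 cell cycle and E2F target genes 23 fell and 0 rose (27 and 0 adjusted over the list alone), with a median log2 fold change of -1.15 (camera, adjusted p = 1.38e-09; adjusted p = 0.236 with an estimated correlation). PLK1, a mitotic kinase, fell from 262 to 63.5 FPKM (log2 fold change -2.01), RRM2, the small subunit of ribonucleotide reductase, from 223 to 72.8 (-1.60), CCNB1, cyclin B1, from 189 to 66.3 (-1.50) and FOXM1, a transcription factor of mitotic genes, from 47.0 to 17.1 (-1.42). The number of these genes that fell was 0 without control replicate 1 and 2, 8 and 13 without depleted replicates 1, 2 and 3, while the median stayed between -1.21 and -1.04 without any 1 library. Of 30 oxidative phosphorylation genes 8 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.51, camera adjusted p = 0.00375; adjusted p = 0.827 with an estimated correlation). UQCRC1 fell by 1.69, CYC1 by 1.45 and COX5A by 1.06 on the log2 scale, whereas COX7C rose by 1.32. The oxidative phosphorylation median was -0.34 without control replicate 2 and -0.33 with the span trend removed, and the call held in both. Of this list 0 fell without control replicate 1 or any 1 depleted replicate, and 22 without control replicate 3. Of 30 ribosomal protein genes 4 fell (RPS2, RPS3, RPS9 and RPL3, by 1.25, 1.27, 1.23 and 1.07) and RPL11 rose by 0.82, and 0 passed adjusted over the list alone (median -0.63, camera adjusted p = 0.0347; adjusted p = 0.911 with an estimated correlation). The ribosomal call was lost without control replicate 2 (median -0.40, adjusted p = 0.0782), depleted replicate 2 (0.132) or depleted replicate 3 (0.0571), with the replicate number as a block (0.069), with a filter of mean FPKM 5 (0.151) and with the span trend removed (median -0.22, adjusted p = 0.203). Of the ribosomal list 0 fell without control replicate 1 or any 1 depleted replicate, 2 without control replicate 2 and 19 without control replicate 3.

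Among early-response genes and p53 targets more members rose than fell, and most did not pass. Of 34 genes with unstable early-response mRNAs 13 rose and 2 fell (14 and 3 adjusted over the list alone; median 0.37, camera adjusted p = 0.00118; adjusted p = 0.236 with an estimated correlation). CYR61 rose from 10.8 to 42.8 FPKM (log2 fold change 1.88), BTG2, an antiproliferative partner of the deadenylase, from 17.8 to 54.5 (1.57), ATF3, a stress-response transcription factor, from 25.6 to 71.6 (1.45) and DUSP1, a phosphatase of MAP kinases, from 15.02 to 41.0 (1.39). DUSP2 fell by 1.79 and KLF2 by 1.15. With the span trend removed the early-response median was 0.79, with 18 that rose and 1 that fell. The number that rose was 2 without control replicate 1 and 8, 8 and 9 without depleted replicates 1, 2 and 3, and 5 fell without control replicate 3. Of 27 p53 targets 10 rose and 1 fell (13 and 2 adjusted over the list alone; median 0.51, camera adjusted p = 0.00701; adjusted p = 0.458 with an estimated correlation). PLK2 rose by 2.2, SESN1 by 1.53 and the death receptor gene FAS by 1.22 on the log2 scale, and DDB2 fell by 0.97. The p53 call was lost without control replicate 3 (adjusted p = 0.061), where 5 fell, and the number that rose was 1 without control replicate 1 and 2, 2 and 3 without depleted replicates 1, 2 and 3. Of 24 genes of the CCR4-NOT complex and deadenylation 4 rose (BTG2, BTG1, DCP1A and CNOT4) and CNOT3 itself fell (6 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 0.0392; adjusted p = 0.827 with an estimated correlation). That call was lost without control replicate 2 (median 0.22, adjusted p = 0.242), depleted replicate 1 (0.0605) or depleted replicate 2 (0.0542), with no filter (0.13) and with the span trend removed (0.0971), and 1 rose without control replicate 1, 2 without control replicate 2 or any 1 depleted replicate, and 15 without control replicate 3.

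Some genes of epithelial junctions and of the epithelial-mesenchymal transition rose, and none of either list fell past the test. Of 26 junction genes 8 rose and 0 fell, likewise adjusted over the list alone (median 0.34, camera adjusted p = 0.0144; adjusted p = 0.236 with an estimated correlation; 0.0918 with no filter; median 0.52 without control replicate 2). The tight junction genes TJP1, OCLN and CLDN4 rose by 1.59, 1.2 and 1.21 on the log2 scale, and KRT7 belongs to this list. Of the junction genes 1 rose without control replicate 1 or any 1 depleted replicate, and 4 fell without control replicate 3. Of 11 genes of the epithelial-mesenchymal transition 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.65, camera adjusted p = 0.027; adjusted p = 0.502 with an estimated correlation). PLAU, a plasminogen activator (1.13), FN1, which encodes fibronectin (0.93), and the receptor kinase gene AXL (0.65) were among those that rose. The call was lost without control replicate 3 (adjusted p = 0.123) or depleted replicate 2 (0.0542), and with no filter, where 24 members were tested, the median was 0.05. In this list 1 gene rose without control replicate 1 or depleted replicate 1, and 2 without depleted replicate 2 or 3. In all, 8 of 24 lists were called with the preset correlation and 0 with an estimated one.

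**Figure D4:**
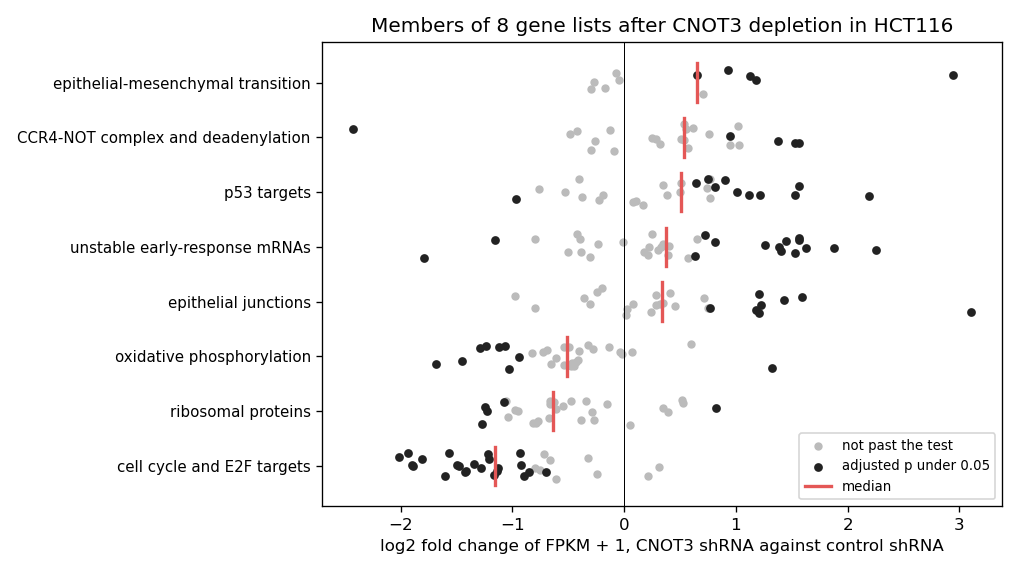
Log2 fold change on the log2(FPKM + 1) scale, CNOT3 shRNA against control shRNA, of each tested member of the 8 called gene lists (points, dark where the adjusted p over all genes is under 0.05) with the list median (bar). Medians run from -1.15 for cell cycle genes to 0.65 for the epithelial-mesenchymal transition.

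The remaining lists did not pass. Among 25 interferon response genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.0717), with IFI44 up by 1.61 and OAS3 down (log2 fold change -0.97). This list was called with the span trend removed (12 rose and 1 fell, median 0.64, adjusted p = 0.00109) and without control replicate 1 (median 0.26, adjusted p = 0.0306), control replicate 2 (0.45, adjusted p = 0.0147) or depleted replicate 1 (0.34, adjusted p = 0.0121). Without control replicate 3 its median was -0.03 (adjusted p = 0.326), and with an estimated correlation the adjusted p was 0.827. Among 34 MYC targets and ribosome biogenesis genes 7 fell (5 adjusted over the list alone; median -0.39, adjusted p = 0.0908), among them the nucleolar methyltransferase gene FBL (-1.29). The MYC list was called without control replicate 2 (median -0.26, adjusted p = 0.0429) and with no filter (adjusted p = 0.0114). Hypoxia and glycolysis genes went both ways, with 7 of 28 that rose and 4 that fell (7 and 6 adjusted over the list alone; adjusted p = 0.916). There SLC2A1 and ADM rose by 1.58 and 1.47, and the glycolytic genes ENO1, PGAM1, ALDOA and GAPDH fell by 0.97, 1.11, 1.04 and 1.00. Cholesterol synthesis genes also divided, with 6 of 25 that rose, HMGCS1 and MSMO1 included, and 4 that fell, SREBF1 and SREBF2 included (7 and 4 adjusted over the list alone; adjusted p = 0.916). Of 19 intestinal stem cell and Wnt target genes SOX9, CD44 and CCND1 rose by 1.81, 1.27 and 1.23 and NOTUM fell by 1.19 (3 and 1 adjusted over the list alone; adjusted p = 0.916). Of 27 genes of the unfolded protein and integrated stress response 5 rose and 5 fell (5 and 10 adjusted over the list alone; adjusted p = 0.595), with DNAJB9 up by 1.32 and PHGDH at -1.26. Of 7 pluripotency factors DNMT3B, TRIM28 and TERT fell and KLF5 rose (3 and 1 adjusted over the list alone; adjusted p = 0.983). Over the 16 lists that did not pass, 40 entries rose and 33 fell. These numbers were 3 and 0 without control replicate 1, 61 and 87 without control replicate 3, 6 and 0 without depleted replicate 1, and 13 and 1 without depleted replicate 2 or 3.

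The lists of tissue and developmental genes did not pass either. Of 7 absorptive colonocyte genes CEACAM1, EMP1 and TSPAN1 rose and CDX2 fell, also adjusted over the list alone (adjusted p = 0.197). Of 16 carcinoma-associated genes 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.451). Of 19 HOX genes 1 rose and HOXC13 fell (1 and 0 adjusted over the list alone; adjusted p = 0.798), and of 14 lineage developmental regulators PAX9 rose and PITX1 fell (0 and 1; adjusted p = 0.732). Of 7 fibroblast and smooth muscle markers ACTA2 rose and FBLN1 fell (1 and 1; adjusted p = 0.929), of 4 endothelial markers MMRN2 fell (0 and 2; adjusted p = 0.228) and of 4 T and B lymphocyte markers PRF1 fell (0 and 1; adjusted p = 0.983), all adjusted over the list alone in parentheses. None of 2 myeloid markers passed over all genes (0 and 1 adjusted over the list alone; adjusted p = 0.451), nor of 2 goblet and enteroendocrine genes (0 and 0; adjusted p = 0.438). Median and mean differed in sign for the hypoxia, stem cell and cholesterol lists (medians -0.25, -0.13 and -0.28, means 0.12, 0.04 and 0.03, tests upward) and for pluripotency factors and lymphocyte markers (medians 0.40 and 0.05, means -0.02 and -0.08, tests downward). For fibroblast markers both were negative and the test was upward.

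The change in expression followed the genomic span of the gene. Across the 11418 tested genes, which are not independent replicates, the log2 fold change correlated with span (Spearman's rho 0.361), and the median rose from -0.46 in the 10% of genes with the shortest loci to 0.38 in the 10% with the longest. Control libraries differed along span as well. The deviation from the control mean had a rho of 0.00748 in control replicate 1, -0.447 in control replicate 2 and 0.451 in control replicate 3. With the trend along span removed from each library, an alternative chosen after seeing the data, 1483 genes rose and 1610 fell, of which 2399 were among the 2828 called above, and the cell cycle list kept a median of -0.91 (camera adjusted p = 6.04e-09).

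**Figure D5:**
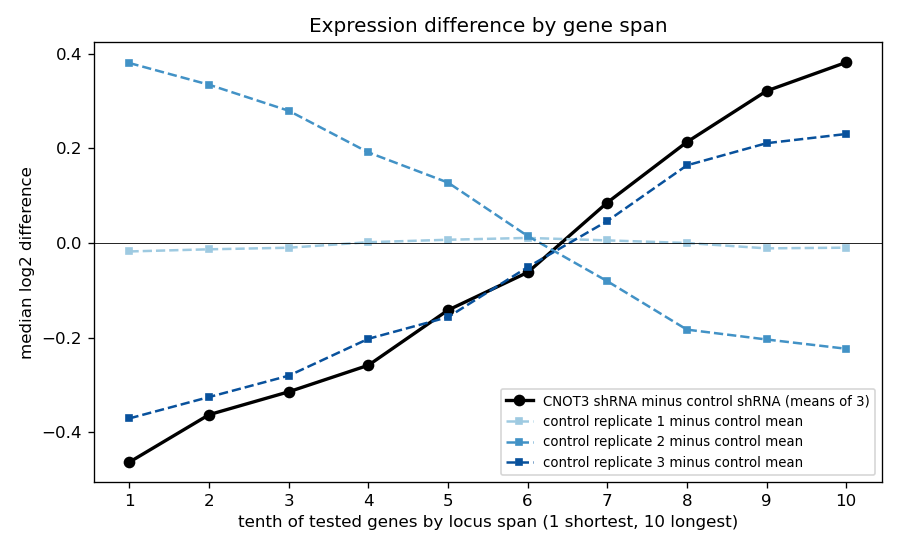
Median log2 difference on the log2(FPKM + 1) scale in 10 equal groups of the tested genes by locus span, for the means of depleted minus control libraries (solid line) and for each control library minus the control mean (dashed lines). The solid line runs from -0.46 to 0.38, and control replicates 2 and 3 run in opposite directions, from 0.38 to -0.22 and from -0.37 to 0.23.

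Genes bound by CNOT3 in carcinoma replicate 9 were then compared with others in the HCT116 data. The 8990 bound genes had a mean log2 fold change of -0.08 ± 0.77 (SD across genes) and the 2104 other genes 0.06 ± 0.74. Of bound genes 907 rose and 1365 fell, and of the others 268 rose and 218 fell. Without control replicate 1 the bound genes that rose and fell were 21 and 20, and without depleted replicates 1, 2 and 3 they were 49 and 35, 83 and 108, and 116 and 188. The difference of -0.15 passed limma's camera at p = 0.0404 (p = 0.254 with an estimated correlation). It did not pass without control replicate 2 (-0.10, p = 0.0724), control replicate 3 (-0.18, p = 0.05003) or depleted replicate 1 (-0.12, p = 0.0641), nor with the span trend removed (-0.11, p = 0.123). In 5 bins of control expression the difference ran from 0.05 in the second bin to -0.16 in the highest, and in the shortest and longest of 5 span bins it was -0.26 and 0.002. The fold change itself fell with control expression. Its mean was 0.40 in both bound and other genes in the lowest bin, and -0.59 and -0.44 in the highest. Control values set these bins and also enter the fold change, so spread between control libraries alone can give such a trend. The filter on the mean of 6 libraries also keeps genes with control values near 0 only if their depleted values were high. Oxidative phosphorylation, ribosomal protein and glycolytic genes, many of them highly expressed, were not compared with genes of like expression. Whether their falls exceed this trend was therefore not tested. Binding and expression came from different sources, a carcinoma and a cell line.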

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

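None of the checks of single samples was chosen after the result was seen, and for the 2 samples below no explanation was tested. In the adenoma group, 1 list had H3K4me2 at 1.44% of gene loci, where the nearest of the other adenomas had 37.3%. The gap was 0.504 of the whole range, above the critical value of 0.466 for 10 samples. In the carcinoma group, the list of replicate 9 held 165218 autosomal peaks, where the next held 82862, a gap of 0.535 of the range. It is the H3K4me2 list that was set against the CNOT3 peaks of the same carcinoma. Such checks were made 12 times, and chance alone marks about 1 in 20 groups.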

How the results depend on the processing

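The alternatives by list format, by removal of the span trend and by omission of small RNA genes, and the use of CNOT3 peaks of carcinoma replicate 9, were chosen only after the results were seen. So was the comparison of H3K4me2 between lesions at the upper 50% of CNOT3 peaks by score (0.129 points, permutation p = 0.947). Main results kept direction and side of the threshold, or stayed within 1.5 times or their spread, in 117 cases, moved further in 48, turned sign in 16 and lost a call in 6. For the exceptions below the cause was not tested. H3K4me2 differences that turned sign passed the threshold in no setting. In pairs with at least 10000 peaks in both lists they were -0.068 for the log2 peak number, -1.17 points for the share at locus ends and -0.476 points at CNOT3 peaks, with 0 loci in more carcinomas. With lists reduced to equal length the difference at CNOT3 peaks was -0.473 with 1 locus in more and 1 in fewer carcinomas, and with 50% of the CNOT3 peak covered it was -0.212. The wider 50% of each list gave 4 loci in more and 7 in fewer carcinomas. A window of 1 kb gave a share difference of -0.0612 and 0 loci in more carcinomas, and one of 10 kb 5 loci in more and 2 in fewer, with PNPLA3 then marked in 1 more carcinoma than adenomas. Pairs sorted by position gave a share difference of -0.0231 and 0 loci in more carcinomas, the other pairs 1 locus and -1.55 points at CNOT3 peaks. Without each pair in turn the ranges were -0.068 to 0.49 for peak number, -1.17 to 2.31 points for the share, 0 to 3 loci in more and 0 to 2 in fewer carcinomas, 0 to 0 lists and -0.758 to 1.29 points at CNOT3 peaks. Without the pairing of lesions (no replicate block) peak number and share had permutation p of 0.727 and 0.889, and no call changed. CNOT3 overlaps with 50% coverage and with the upper 50% of scores were 4.53% and 13.4% for HCT116 in carcinoma, 67.5% and 58.5% for carcinoma in HCT116, and 64.7% and 96.0% for CNOT3 in H3K4me2. The share at ends was 71.8% with the upper 50% of scores and 54.9% with 1 kb, and the former gave 2 gene lists bound more or less often. RNA calls fell to 1812 with no filter (925 lower, 887 higher), where more genes were tested, and a filter of mean FPKM 5, with fewer tested, left 735 higher and 1435 lower. An estimated correlation left 0 lists. Without each RNA library in turn the ranges were 54 to 6641 genes (30 to 2940 higher, 24 to 3701 lower), 5 to 9 lists and -0.18 to -0.10 for bound genes. The difference of bound genes lost its call with the span trend removed (-0.11), the upper 50% of scores (-0.11), a window of 1 kb (-0.12) and without control replicate 2 (-0.10), control replicate 3 (-0.18) or depleted replicate 1 (-0.12). RNA replicates with the same number did not deviate together (correlations -0.112, 0.118 and -0.152). The replicate number as a block gave 2777 genes (1267 higher, 1510 lower) and 7 lists. Of 92 named RNA genes 24 kept their call in each of the 14 alternatives that tested them, and none changed sign there. The filter of mean FPKM 5 tested 81 of them, the omission of small RNA genes 80, and the other alternatives 92. Single genes, loci and lists kept their verdict in 1376 cases, lost a call in 285, moved in 37 and turned sign in 1, PNPLA3 above. CNOT3 peaks of HCT116 shared with both carcinomas, binding in HCT116 alone or with both carcinomas, and omission of carcinoma replicate 2 or 9 were not run, since the lists of HCT116 and carcinoma replicate 2 were on another assembly and replicate 9 was the single list left for these tests. A stricter H3K4me2 list gives no peak number of its own, since it takes 50% of each list. Depth is unknown for the peak lists, so absence of a peak does not show absence of the mark.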

Other observations

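The gene families below, both tests of the span trend, the test of neighbouring interferon genes and the count of label swaps for H3K4me2 were chosen only after the results were seen. Several keratin, serpin and laminin genes rose after CNOT3 depletion. Of 17 keratin genes 8 rose and 2 fell (median log2 fold change 0.72, camera adjusted p = 0.00218 over 19 families; adjusted p = 0.773 with an estimated correlation), with KRT80 from 2.86 to 13.9 FPKM and KRT81 from 3.97 to 11.9. The keratins that rose were 2 without control replicate 1 and 3, 2 and 2 without depleted replicates 1, 2 and 3, with 0 that fell. Of 12 serpin genes 5 rose and 0 fell (median 0.67, adjusted p = 0.0101; adjusted p = 0.294 with an estimated correlation), and of 8 laminin genes 3 rose, LAMB3 (1.99) and LAMA3 (1.39) among them (adjusted p = 0.015; adjusted p = 0.294 with an estimated correlation). Families were taken by gene symbol alone, so they can hold genes that are not subunits or members. Medians were negative for complex I genes by symbol (4 of 46 fell, median -0.47, camera adjusted p = 0.00374) and mitochondrial ribosomal proteins (11 of 78 fell, median -0.39, camera adjusted p = 0.0182). The same held for genes with MCM symbols (6 of 10 fell, median -0.93, camera adjusted p = 0.0391). With an estimated correlation the camera adjusted p was 0.773, 0.773 and 0.294. MCM3AP, which fell by 0.94, was counted with the MCM genes and is not an MCM helicase gene. The complex I median was -0.29 without control replicate 2 and -0.25 with the span trend removed, and the mitochondrial ribosomal median -0.25 and -0.23. The mitochondrial ribosomal call was lost with the span trend removed (adjusted p = 0.165), with a filter of mean FPKM 5 (0.173) and without depleted replicate 2 (0.0625), and the MCM call without control replicate 3 (0.333). Without control replicate 1, 1 serpin and 0 laminins rose and 0 complex I, mitochondrial ribosomal or MCM genes fell. Without depleted replicates 1, 2 and 3, 2 serpins rose in each case, 0, 2 and 3 laminins rose, 0, 1 and 2 MCM genes fell, and 0 complex I or mitochondrial ribosomal genes fell. Without control replicate 3, 31 complex I and 42 mitochondrial ribosomal genes fell, 5 laminins rose and 3 MCM genes rose. Histone genes went both ways, with 9 of 27 that rose and 7 that fell (adjusted p = 0.597). HIST1H2AC rose from 9.01 to 45.5 FPKM and HIST1H2BD from 11.3 to 44.3, whereas H1F0 fell from 342 to 82.7. Without control replicate 1, 2 histone genes rose and 1 fell, and without depleted replicate 1, 3 and 1.

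Loci with CNOT3 or H3K4me2 in tissue were more often expressed in HCT116. Of genes bound by CNOT3 in carcinoma replicate 9, 65.03% had at least 1 FPKM in control cells (median 3.72), against 19.9% of unbound genes. The share was 8.80% for genes at loci with H3K4me2 in 0 of the 20 lists, 18.5% for 1 to 9 lists, 60.8% for 10 to 17 and 72.3% for 18 to 20. H3K4me2 lay in at least 18 lists at 4905 loci (24.96%) and in none at 3952 (20.1%).

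Cell cycle genes fell after CNOT3 depletion with a median of -1.15, and the span trend and a single library were weighed as sources of the fall. With the span trend of each library removed the median was -0.91, over 0.5 times the original, so that trend does not account for most of the fall. Without any 1 of the 6 libraries the median was at most -1.04 and at least -1.21, which argues against a single library as its source. A fall shared by highly expressed genes was not weighed. In the highest of 5 bins of control expression the mean log2 fold change was -0.59 for genes bound by CNOT3 and -0.44 for others. Those bins were set by control values that also enter the fold change, so they cannot show by themselves that highly expressed genes fell. A lower growth rate or loss of CNOT3 activity may also explain the fall, and the data do not separate these explanations. A second shRNA was not analysed here.

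The rise of the fold change with gene span stayed open between the libraries and the depletion. A control library alone deviated along span with a rho of 0.451, more than the 0.361 of the fold change, so differences between libraries without depletion could give a trend of this size. Differences between 2 control libraries had a rho of 0.421 to 0.455 in size. The 9 differences between a depleted and a control library had a rho of 0.0649 to 0.423, with 0 at or below 0, but they share 6 libraries and none exceeded the largest between controls. An effect of depletion therefore cannot be told apart from differences between libraries with 3 per group, and GC content was not tested for lack of a genome sequence.

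Interferon response genes, a pattern noticed in the results, were seldom bound by CNOT3 in carcinoma replicate 9 (37.5% of 24). A missing H3K4me2 peak does not account for it, since 100% of the list lay at loci with H3K4me2 in that carcinoma. So did 94.8% of the other genes, and peak lists give no level of the mark, so weaker active chromatin stays open. Of the genes nearest in FPKM in HCT116 controls 82% were bound, but expression in that carcinoma was not measured, so low expression there stays open. With members within 500 kb joined, 8 of 17 groups were bound (47.1%, 95% Wilson interval 26.2 to 69.0), which includes the 65% that counting neighbours separately would need at least, so this cannot be told apart from the pattern with so few groups. The pattern rests on 1 library, CpG content was not tested, and no biological explanation was tested.

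Chance could not be examined fully for RNA, since 6 libraries make 10 splits and no share under 0.05 can be had. The real split called 2828 genes and the highest of the others 3, so that 1 split reached the real count. For gene lists the real split called 8 and the highest other 10, and 3 splits called as many. For bound genes the real difference was 0.149 in size and the highest other 0.111, with 1 split as large. For H3K4me2, 97 of 100 swaps of the lesion labels within pairs gave as many loci as the 2 found, the highest other 53 and the median 9, so chance is not excluded for RSPO2 and TRIM29.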
